A study of Rattus norvegicus with 4 samples.

How the data were processed

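Histone H3 trimethylated at lysine 9 (H3K9me3), the modification that marks constitutive heterochromatin, was mapped by CUT&Tag in adipose-derived mesenchymal stem cells of Sprague Dawley rats. In CUT&Tag an antibody directs a transposase to the chromatin it binds, and the DNA cut there is sequenced. Cells in medium free of branched-chain amino acids (BCAA: leucine, isoleucine and valine) received vehicle or 3.432 mM BCAA for 12 h in the presence of 100 µM hydrogen peroxide. Each condition gave 1 library with the H3K9me3 antibody and 1 with normal rabbit IgG, so 4 libraries formed 4 groups of 1. Groups were taken from the sample titles.

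The deposited data were 1 list of broad peaks per library, called per library and not on pooled samples. BWA, MACS2, deepTools, ChIPseeker and the rn6 build are named in the submitters' processing notes, without versions, roles or settings. Whether the IgG libraries served as controls in calling is not given in the sources used here. Each deposited peak carried a whole-number score, a fold enrichment, which is the linear ratio of signal to local background given by the authors, and the −log10 p and −log10 q of the authors' peak caller. The score was 10 times the deposited −log10 q, rounded down, and was not used further. Fold enrichment and −log10 q described and ranked peaks within a list. Common limits on them were also applied to both lists, and shared pairs were ranked by the lower of their vehicle and BCAA fold enrichments. Each value is set against the background of its own library, so a common limit need not select the same sites in both lists. Positions are 1-based rn6 coordinates.

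Lists were compared with bedtools 2.31.1, and a peak counted as met when a peak of the other list overlapped it by at least 1 bp. Shares carry exact (Clopper-Pearson) 95% binomial intervals, and ratios of counts carry the interval of the corresponding binomial share. The interval of the covered-length ratio came from 1000 bootstrap draws of peaks. All intervals cover counting error only. With 1 library per group no difference between conditions has a replicate check, and no p-value was computed. Chance overlap was taken from 1000 random placements of the BCAA peaks on their own chromosomes. Chromosome lengths of rn6 were not used here, so the highest peak end in either H3K9me3 list stood for the length, and chromosomes were compared by their share of the peaks on chromosomes 1 to 20, X and Y.

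The lists give no read totals. Depth was therefore read from the peak values. Where the pileup is the same along a peak, the fold enrichment equals (n + 1)/(λ + 1) and the p-value is the Poisson tail above n, for n overlapping fragments and a background λ. Whole n with −log10 p matched within 0.001 were found for 60.5% of the vehicle peaks and 50.2% of the BCAA peaks, against 7.04% and 5.00% after the p-values had been permuted among peaks. On simulated peaks, n was recovered for 100% of 8929 and 100% of 16704, the numbers of peaks in the vehicle and BCAA lists. Only these numbers came from the lists. The simulated values were made with the same formulas and set fragment numbers and backgrounds. The simulation therefore checks the calculation and not whether the formulas hold for the deposited peaks. Among peaks of 3 or more fragments, λ was a whole multiple (within 0.05) of 119 bp per 10 kb for 84.9% of vehicle peaks and of 166 bp per 10 kb for 74.8% of BCAA peaks, against 13.8% and 12.2% for uniformly drawn values. The conversion of λ into fragments per 10 kb assumes the caller's usual formulas and a 10 kb local window. It also assumes that λ came from the H3K9me3 library itself and not from an IgG control. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.

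Before the data were examined, the named regions were set as up to 12 IgG peaks, the 10 peaks of highest fold enrichment on assembled chromosomes found in only 1 H3K9me3 list, the 5 overlapping pairs whose lower fold enrichment was highest, and the 5 longest peaks of each H3K9me3 list. Stricter limits of −log10 q (2 and 5), fold enrichment (5) and width (1000 bp), equal list lengths, assembled chromosomes alone, removal of peaks at IgG peaks, merging within 5 kb and other definitions of a shared peak were set as alternatives at the same time. An annotation and a genome sequence of rn6 were not used here, so no gene, promoter or repeat is assigned to any peak, and the comparisons of promoters, repeats and fixed gene lists were left out.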

Results

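The effect of branched-chain amino acids on heterochromatin under oxidative stress was examined through H3K9me3 peaks in rat adipose-derived mesenchymal stem cells, which are stromal progenitors isolated from fat. Cells were exposed to 100 µM hydrogen peroxide with vehicle or with 3.432 mM BCAA for 12 h. The H3K9me3 lists held 8929 peaks in the vehicle library and 16704 in the BCAA library, and the IgG lists held 16 and 11. There were no replicates, so no difference between vehicle and BCAA below has a replicate check. Fold enrichments are the authors' values.

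IgG, an antibody without a chromatin target, was used to look for background peaks. Of the 16 peaks of the vehicle IgG list, 5 lay on the mitochondrial chromosome, and so did 4 of the 11 of the BCAA IgG list. Mitochondrial DNA carries no histones. The H3K9me3 lists held 5 and 4 mitochondrial peaks too, at fold enrichments of 1.34 to 2.47 with vehicle and 1.45 to 2.10 with BCAA. The strongest IgG peak in both lists lay on the unplaced scaffold KL568292.1, at positions 1218 to 1507 in the vehicle IgG library (fold enrichment 17.95) and 1222 to 1451 in the BCAA IgG library (10.8). On chromosome 1, positions 36361173 to 36361365 and 180644836 to 180645004 were called with vehicle IgG (10.1 and 9.005), and positions 36361173 to 36361389 and 180644860 to 180645041 with BCAA IgG (10.8 and 7.03). These 3 sites were peaks in both H3K9me3 lists as well. Chromosome 1 positions 180858084 to 180858260 and chromosome 13 positions 33504477 to 33505057 were called only with BCAA IgG (7.98 and 6.50) and also carried peaks in both H3K9me3 lists. The vehicle IgG peaks on scaffolds KL568304.1 (6307 to 6789, fold enrichment 6.56) and AABR07022335.1 (112 to 567, 6.02) were met by vehicle H3K9me3 peaks and by no BCAA peak. Those on chromosome 10 (91745066 to 91745370) and chromosome 11 (59070804 to 59071179), each at 4.71, were met by neither. Outside the mitochondrial chromosome, 7 of 8924 vehicle H3K9me3 peaks (0.0784%, 95% interval 0.0315 to 0.162%) and 5 of 16700 BCAA peaks (0.0299%, 0.00972 to 0.0699%) lay at an IgG peak. The lowest −log10 p of an IgG peak was 7.68 with vehicle and 8.11 with BCAA, against 4.33 and 3.98 in the H3K9me3 lists. The IgG lists therefore held no background as weak as the weakest H3K9me3 peaks, and the small overlap does not measure the specificity of those.

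The BCAA library had more H3K9me3 peaks and more covered sequence than the vehicle library. The ratio of peak numbers was 1.87 (95% interval 1.82 to 1.92). Background depth read from the peak values was at least 1.93 times higher with BCAA under the caller's usual settings. This holds if no IgG control was used in calling, which is not known here. The ratio of peak numbers therefore does not show that the number of H3K9me3 sites rose. Values of 53.4% of vehicle peaks and 38.9% of BCAA peaks gave exactly 2 fragments. Peaks covered 1609 kb with vehicle and 3962 kb with BCAA, a ratio of 2.46 (2.39 to 2.55). Mean width was 180 bp against 237 bp. The conversion of λ took each fragment to span 119 bp with vehicle and 166 bp with BCAA. Width and covered length were thus not on a common scale, and do not separate an effect of BCAA from fragment length. Mean fold enrichment was 3.60 and 3.71, each on the background of its own library and so not compared. Most peaks were short. Median width was 154 bp (quartiles 138 and 171) with vehicle and 187 bp (174 and 211) with BCAA, and only 30 and 131 peaks reached 1000 bp. The shortest peak was 119 bp with vehicle and 163 bp with BCAA, and 63.1% of the vehicle peaks were shorter than any BCAA peak. The number ratio was 4.37 for peaks of at least 1000 bp and 5.06 when both lists were held to 163 bp, a limit chosen after the data had been seen that removes vehicle peaks only. It was 1.51 at −log10 q of at least 2 and 1.54 with a common p limit, and the covered-length ratio was 1.46 with lists of equal length.

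**Figure D1:**
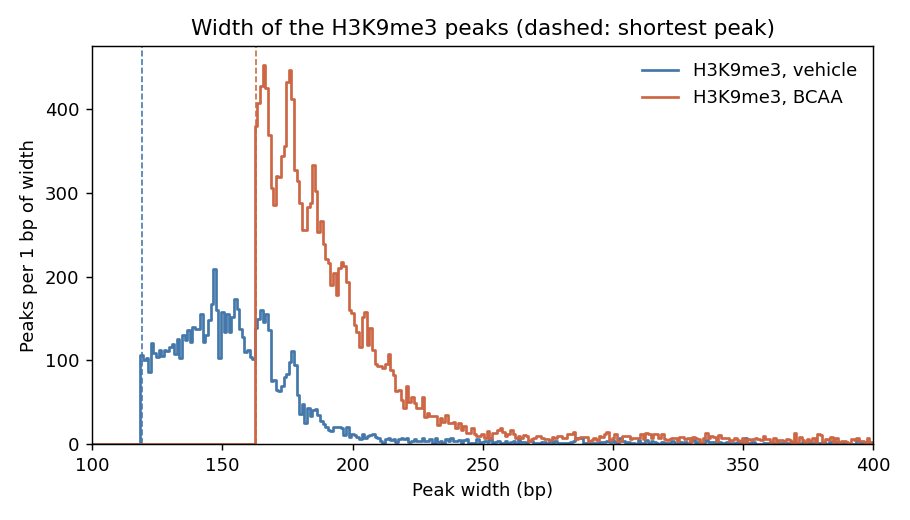
Number of H3K9me3 peaks (vertical axis) at each width in bp (horizontal axis, 100 to 400 bp) in the vehicle and BCAA libraries, 1 library each, with dashed lines at the shortest peak of each list. The vehicle list starts at 119 bp and the BCAA list at 163 bp.

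The longest peaks outside the mitochondrial chromosome reached a few kilobases and were shared by both libraries. With vehicle they lay on chromosome 1 (99054206 to 99056607, 2402 bp, fold enrichment 6.24), chromosome 19 (49377271 to 49379261, 1991 bp, 4.51) and chromosome 1 (56035812 to 56037782, 1971 bp, 4.62). With BCAA they lay on chromosome 12 (3350886 to 3354371, 3486 bp, 4.23), chromosome 18 (38414261 to 38417191, 2931 bp, 6.11) and chromosome 1 (56035155 to 56038049, 2895 bp, 3.50, and 180925852 to 180928730, 2879 bp, 5.24). The remaining 3 of the 10 were mitochondrial, at 12054 to 15886 and 6048 to 9022 with vehicle and at 12073 to 15888 with BCAA.

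Few peaks were shared between the conditions. A BCAA peak met 1512 of the 8929 vehicle peaks (16.9%, 95% interval 16.2 to 17.7%), and a vehicle peak met 1472 of the 16704 BCAA peaks (8.81%, 8.39 to 9.25%). On assembled chromosomes 1475 vehicle peaks were met, 68.0 times the mean of 21.7 in 1000 random placements, of which the highest gave 37. Sharing rose with peak strength. Among vehicle peaks, 7.13% (5.79 to 8.68%) were met at −log10 q under 1.5 and 86.6% (71 of 82, 77.3 to 93.1%) at 20 or more. Among BCAA peaks the corresponding shares were 1.86% (1.58 to 2.18%) and 98.4% (180 of 183, 95.3 to 99.7%). With both lists held to −log10 q of at least 5, the shares of vehicle and BCAA peaks met were 67.3% and 33.3%. Overlap was then 1844 times the random mean. With 337 vehicle peaks met at that limit, this ratio rests on a very small random mean and is not set against 68.0. Among all peaks, the shares were 10.8% and 5.75% when a reciprocal overlap of 50% was required.

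**Figure D2:**
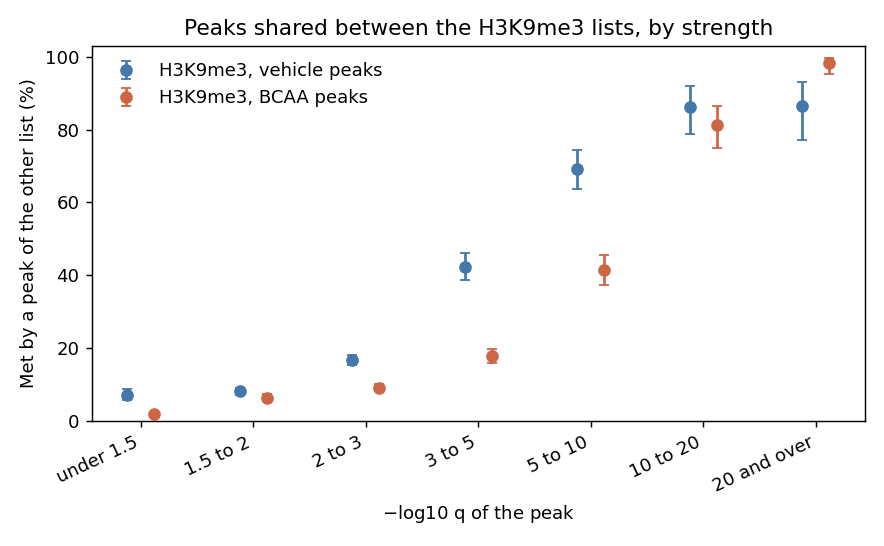
Percent of H3K9me3 peaks met by a peak of the other list (vertical axis) by class of −log10 q (horizontal axis) for the vehicle and BCAA libraries, with exact 95% binomial intervals. The share rises from 7.13% to 86.6% of vehicle peaks and from 1.86% to 98.4% of BCAA peaks.

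The shared sites of highest enrichment were short. On chromosome 1 the vehicle peak at 270803 to 270975 (fold enrichment 38.2) overlapped a BCAA peak at 270801 to 270975 (29.8), and the vehicle peak at 36361172 to 36361390 (34.8) overlapped one at 36361171 to 36361390 (28.1). The others were chromosome 16, 66322858 to 66323067 with vehicle (29.4) and 66322852 to 66323075 with BCAA (26.6), chromosome 1, 180858068 to 180858335 (30.4) and 180858044 to 180858364 (26.3), and chromosome 10, 98727739 to 98727934 in both (25.3 and 24.9). The sites at 36361172 and 180858068 of chromosome 1 also carried IgG peaks.

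Of the 10 vehicle peaks of highest enrichment without a BCAA peak, the first lay on chromosome 18 (47037721 to 47037839) at a fold enrichment of 48.9. It was followed by chromosome 1 (282525818 to 282525945, 36.8), chromosome 7 (116306867 to 116307026, 34.9), chromosome 6 (11029012 to 11029168, 31.4) and chromosome 7 (104099439 to 104099567, 29.3). The next were chromosome 15 (67199686 to 67199813, 27.9), chromosome 4 (80790589 to 80790717, 27.3), chromosome 9 (46937384 to 46937544, 15.4), chromosome 11 (83225844 to 83225987, 13.5) and chromosome 7 (99168178 to 99168304, 13.4). All 10 were between 119 and 161 bp wide and so shorter than the shortest BCAA peak of 163 bp. The BCAA peaks of highest enrichment without a vehicle peak were wider, from 178 to 421 bp. They lay on chromosome 7 (22260827 to 22261229, fold enrichment 15.4), chromosome 1 (103137113 to 103137319, 13.6), chromosome 17 (71386406 to 71386611, 12.5, and 44301702 to 44301895, 12.1) and chromosome 7 (143857130 to 143857311, 11.3). The rest were chromosome 1 (187550255 to 187550432, 11.1), chromosome 10 (83962053 to 83962390, 10.98), chromosome 6 (43544621 to 43545041, 10.7), chromosome X (119954388 to 119954610, 10.5) and chromosome 15 (107545329 to 107545514, 10.2). None of these 20 peaks overlapped an IgG peak.

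Both lists had similar shares of their peaks on most chromosomes. Of 22 chromosomes, X alone had a share of peaks whose interval excluded equality between the libraries, at 3.21% of vehicle peaks (280) and 3.81% of BCAA peaks (618), a ratio of 1.19 (1.03 to 1.37). Up to about 1.1 of 22 such intervals exclude equality by chance if peaks fall independently, and clustered peaks could give more. With lists of equal length the ratio on X was 1.03 (280 and 289 peaks, 0.875 to 1.22), and the interval no longer excluded equality. The lowest ratio was on chromosome 10, at 0.881 (0.768 to 1.01), with 335 and 549 peaks. Chromosome 1 held the most peaks in both lists, 1076 and 1899, in counts not divided by chromosome length. Unplaced scaffolds held 214 vehicle and 497 BCAA peaks, which set against the peaks on assembled chromosomes gave a ratio of 1.25 (1.06 to 1.47). The 4 scaffolds with the most peaks, KL568162.1, KL568139.1, KL568161.1 and KL568157.1, held 89 and 236 of them, and the other 97 held 125 and 261, a ratio of 1.12 (0.9035 to 1.401). On X the ratio was 0.931 for peaks of −log10 q of at least 5, which numbered 17 and 30 (0.497 to 1.80).

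**Figure D3:**
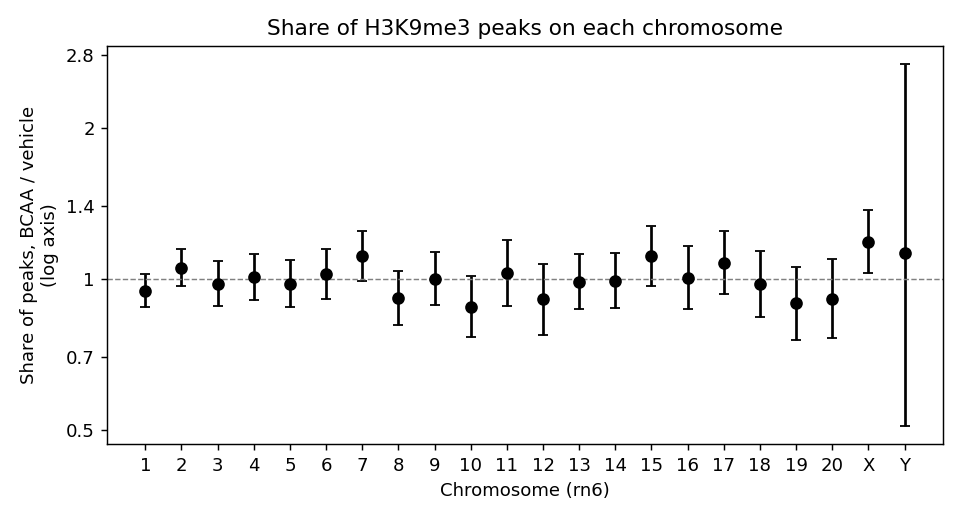
Ratio of the share of H3K9me3 peaks in the BCAA library to the share in the vehicle library (vertical log axis) for each rn6 chromosome (horizontal axis), with 95% binomial intervals and a dashed line at 1. The interval lies above 1 on X, at 1.03 to 1.37. Up to about 1.1 of 22 intervals exclude 1 by chance if peaks fall independently.

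By vehicle and BCAA peaks together, the densest 1 Mb interval and the next lay side by side on chromosome 1. That chromosome held 52 vehicle and 57 BCAA peaks from 180 to 181 Mb, and 45 and 63 from 181 to 182 Mb. Genome-wide medians were 3 and 5 peaks per 1 Mb. These intervals were chosen after their values had been seen. Between 180.5 and 182 Mb the vehicle peaks numbered 91 and covered 26095 bp, the BCAA peaks numbered 116 and covered 54221 bp, and the IgG lists held 1 and 2 peaks.

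**Figure D4:**
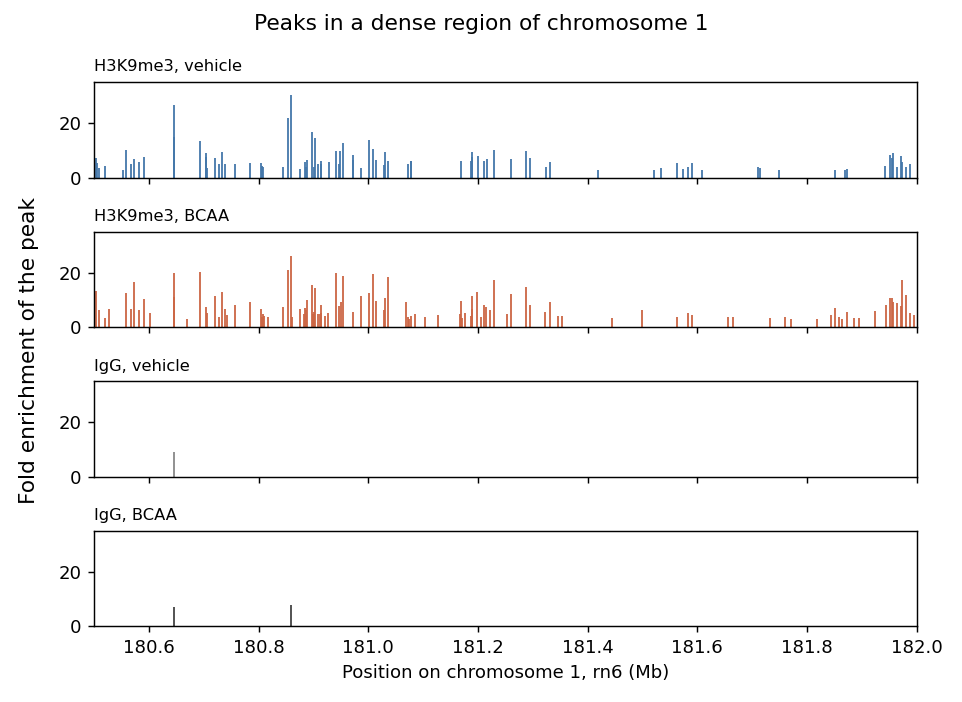
Peaks between 180.5 and 182 Mb of rn6 chromosome 1 (horizontal axis) in the 4 libraries, each drawn as a line at its centre with its height at the authors' fold enrichment (vertical axis), which is comparable within a panel only. The H3K9me3 libraries show 91 and 116 peaks and the IgG libraries 1 and 2.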

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

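The results for strong peaks and all alternatives that use a common p limit, a common shortest length, peaks without 2-fragment peaks or −log10 q of at least 20 were chosen after seeing the data. Under all 12 alternatives to each, the BCAA list stayed longer and covered more than the vehicle list. None of these alternatives evened out the depth or the fragment length of the libraries. The kept direction therefore does not separate an effect of BCAA from either. The cause of the shifts below was not tested, except where the list is shortened by construction. The peak number ratio was 1.51 at −log10 q of at least 2, 1.92 at 5, 2.23 at 20, 2.20 at fold enrichment of at least 5 and 4.37 at 1000 bp or more. It was 1.54 with a common p limit, 5.06 with a common shortest length, which by construction removes vehicle peaks only, 4.17 with both and 2.45 without 2-fragment peaks. The covered-length ratio was 2.05 at −log10 q of at least 2, 2.38 at 5 and 4.06 at 1000 bp, and with the latter 4 settings 2.04, 4.88, 4.03 and 3.08. It was 1.46 with lists of equal length and 2.37 after merging within 5 kb. The fold enrichment limit left it within its interval.

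The share of vehicle peaks met was 24.9% at −log10 q of at least 2, 67.3% at 5, 57.4% at fold enrichment of at least 5 and 73.3% at 1000 bp. It was 15.5% with equal lists, 16.1% after merging, 16.2% with a common p limit, 30.5% with a common shortest length, 29.6% with both and 29.4% without 2-fragment peaks. Requiring 50% of the peak gave 15.3%, reciprocal 50% gave 10.8% and a peak within 5 kb gave 25.1%. The share of BCAA peaks met was, at the same 4 limits, 15.9%, 33.3%, 25.3% and 16.8%. It was 15.1% with equal lists, 10.2% with a common p limit, 5.92% with a common shortest length, 6.98% with both and 11.6% without 2-fragment peaks. The overlap definitions gave 5.98%, 5.75% and 13.6%. Using assembled chromosomes alone or leaving out peaks at IgG peaks left these 4 results within their intervals.

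Overlap was 50.9 times chance after merging and 1844 times at −log10 q of at least 5, where the random mean was very small. The share of peaks on X turned from higher to lower in the BCAA list, at 0.931, at −log10 q of at least 5, where 17 and 30 peaks remained. It was 1.03 with lists of equal length (280 and 289 peaks), where the interval of 0.875 to 1.22 included equality, and 1.15 by covered length. The 3 alternatives for chromosome 10 stayed within its interval. Each IgG list held 4 peaks at −log10 q of at least 5. Promoter, repeat and gene-list results and random placement outside assembly gaps were not run. No paired analysis was possible because each group had 1 library. Of peaks at −log10 q of at least 20, 98.4% with BCAA and 86.6% with vehicle were met. At 10 these shares were 89.6% and 86.4%, with 50% of the peak 83.6% and 85.4%, and with reciprocal 50% 83.1% and 65.9%. Read totals were not used here. A site missing from a list can be undetected or absent, and the lists do not tell which.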

Other observations

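The tests in this part were all chosen after the result they bear on had been seen. Part of the H3K9me3 peaks of both libraries lay in a small number of dense intervals. Besides chromosome 1 from 180 to 182 Mb, the densest 1 Mb intervals were chromosome 1 from 55 to 56 Mb (37 vehicle and 53 BCAA peaks) and from 54 to 55 Mb (20 and 29), chromosome 15 from 5 to 6 Mb (26 and 45), chromosome 13 from 33 to 34 Mb (28 and 39), and chromosome 9 from 12 to 13 Mb (20 and 33) and from 8 to 9 Mb (18 and 33). The 20 intervals richest in vehicle peaks of −log10 q of at least 5, out of 2793, held 23.0% of such BCAA peaks (214 of 931, 95% interval 20.3 to 25.8%). The 20 richest in BCAA peaks held 29.3% of such vehicle peaks (144 of 491, 25.3 to 33.6%). Across 1 Mb intervals, which are not independent replicates, peak counts of the libraries had a Pearson r of 0.659 and a Spearman rho of 0.407. These moved with interval size, to 0.369 and 0.207 at 100 kb and 0.780 and 0.580 at 5 Mb. For peaks of 2 fragments in 1 Mb intervals they were 0.10 and 0.0999, and for peaks of −log10 q of at least 5 they were 0.898 and 0.433.

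The ratio of BCAA to vehicle peaks was lower in the densest intervals. In each of the 8 densest of 1 Mb it lay under the genome-wide 1.87, and pooled it was 1.43 (246 and 352 peaks, 95% interval 1.21 to 1.69). Taken singly, only chromosome 1 from 180 to 181 Mb had an interval that excluded 1.87 (0.739 to 1.63). The BCAA peak there at 180703088 to 180704713 spanned the vehicle peaks starting at 180703392 and 180704362. Whether such joined peaks lowered the ratio of counts was not tested. Of 553 intervals of 5 Mb with at least 20 peaks, 22 (3.98%) had a ratio whose 95% interval excluded the genome-wide ratio, 10 above it and 12 below. For peaks that fall independently, chance alone gives up to about 27.6 such intervals. As this is an upper limit for independent peaks, and clustered peaks could give more, the count cannot tell whether the number exceeds chance. The extremes of the 553 were, at the high end, chromosome X from 60 to 65 Mb (2 vehicle and 18 BCAA peaks), chromosome 1 from 200 to 205 Mb (3 and 25) and chromosome 14 from 85 to 90 Mb (4 and 30). The lowest ratio was on chromosome 10 from 60 to 65 Mb (20 and 15).

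The longer BCAA list is consistent with deeper sequencing. The lowest background was 3.86 fragments per 10 kb in the BCAA list and 2.0 in the vehicle list, where it is an upper limit. Background depth was thus at least 1.93 times higher with BCAA under the caller's usual settings, if calling used no IgG control. A lower p limit of the BCAA list was not the whole cause, since the number ratio was 1.54 (95% interval 1.499 to 1.582) with the same p limit in both lists. An effect of the BCAA treatment cannot be told apart from depth, because there was 1 library per condition.

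The small shared part of the lists may reflect sampling of the same sites with few fragments. The longer minimum length of the BCAA list may add to this, as 63.1% of vehicle peaks were shorter than any BCAA peak. With both lists held to 163 bp, which removes vehicle peaks only, the share of vehicle peaks met was 30.5% against 16.9%. That of BCAA peaks was 5.92% against 8.81%. Peak length was not separated from fragment number. Values of 53.4% of vehicle peaks and 38.9% of BCAA peaks gave exactly 2 fragments, of which 5.42% and 1.22% were met, while 86.6% of vehicle peaks of −log10 q of at least 20 were met. Uniform chance placement of all 2-fragment vehicle peaks was argued against, since 249 were met on assembled chromosomes, 23.4 times the random mean and above the highest placement of 25. These were 5.38% of the 4624 there, so the test cannot exclude chance placement of most of them. The random placements did not avoid assembly gaps. Relocation of a large part of the strong sites was argued against, as 1.64% of BCAA peaks of −log10 q of at least 20 lacked a vehicle peak (3 of 183, up to 4.72%), although the share met was 89.6% at 10 and 83.1% where a reciprocal overlap of 50% was required. New weak sites with BCAA would give the same rise of sharing with strength in the BCAA list and stay open for it. They would not leave weak vehicle peaks unmet. They therefore do not account for the rise in the vehicle list, from 7.13% at −log10 q under 1.5 to 86.6% at 20 or more. Loss of weak sites with BCAA would leave weak vehicle peaks unmet. It was not tested and stays open for that list.

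Strong vehicle peaks without a BCAA peak may result from the longer minimum length of the BCAA list. Of 11 such peaks at −log10 q of at least 20, 90.9% were shorter than 163 bp, against 2.82% of the 71 met ones. Loss of the peak under BCAA was argued against for strong vehicle peaks long enough for the BCAA list, of which 1.43% (1 of 70, up to 7.70%) were unmet. Of the 12 shorter ones, 83.3% (51.6 to 97.9%) were unmet. The BCAA list held no peak under 163 bp, so short sites could go unmet without any loss of the mark. Both contrasts come from the same 82 peaks and are not separate tests. Loss at the narrow sites alone was not tested. The 1 long unmet peak lay on scaffold KL568201.1, positions 1 to 681.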
